A study of Mus musculus with 6 samples.

How the data were processed

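Total RNA from sorted spleen γδ T cells of Eomes reporter mice was measured on 6 one-colour Agilent arrays, 3 of GFP-positive and 3 of GFP-negative cells. Per the labels, each of the 3 sorts pooled 4 to 6 spleens, from mice of 9, 9.5 and 7.5 weeks for the samples numbered 1, 2 and 3. B220-, CD4- and CD8β-bearing cells were depleted, CD3-positive, TCRγδ-positive and TCRβ-negative cells were then sorted by GFP, and RNA was amplified once before labelling. Per the file headers, the signal values are intensities on a linear scale, made with Agilent Feature Extraction 10.7.3.1 by background subtraction with spatial and multiplicative detrending, without normalization between arrays. The table of values that the authors deposited holds 1 intensity per probe and array, scaled so that the 75th percentiles were 1497 to 1506, with minima of 15 to 17 and medians of 58 to 77. Its log2 offset from the scanner intensity was constant within an array, with an interquartile range of at most 0.0034. The spots of the scanner files also hold other columns, the 0 or 1 flags for signal well above background, saturation and outliers, which per the file headers come from the same software.

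Each array had 162570 spots, of which 4854 were controls, and 39429 probes with 4 spots each entered the analysis. The spots of a probe were averaged as log2 processed intensity without spots marked as outliers, and the 75th percentile of the array was subtracted. A probe counted as measured on an array where at least 50% of its spots were well above background. Gene names came from the RefSeq accession of the probe for 27508 probes, which renamed 2017, and 11921 probes kept the name in the scanner file. This gave 30342 names, 19890 of them plain symbols. The probe with the highest mean stood for each gene, and genes measured on at least 3 of the 6 arrays were tested, which left 16413, 12215 of them plain symbols. Probe positions are those of the scanner files, in the mm9 build. Of the named genes, 25 had more than 1 probe. Counting only probes well above background on all 3 arrays of a group, 2 of these, Hspa8 and Hk1, had probes of opposite direction, and dimmer probes of Gja5, Cd44, Ltbp1, Siglech and Rora also pointed the other way. The brightest Hk1 probe lies on chromosome 5 and its other probes on chromosome 10, so no value is given for Hk1.

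Groups were compared with limma 3.58.1 in R 4.3.3 (statmod 1.5.0 and the data.table package, version 1.17.8), with a linear model of group only, moderated variances, and Benjamini-Hochberg adjusted p-values with a threshold of 0.05. A test of single genes by exact permutation of 3 against 3 arrays cannot give a two-sided p below 0.1. Where no probe of a gene was well above background on any array of 1 group, the fold is given as a bound at a background floor ("at least"). Each array of that group was then set to the lowest signal that counted as well above background on it, or to its own signal where that was higher. The bound holds for that floor only, because some probes not well above background had signals above it. For the named genes with such a bound, some other settings gave smaller differences. Among called genes, 17 higher and 61 lower had only such a bound. Gene lists were tested with limma's camera with a preset correlation of 0.01 and, as an alternative, an estimated correlation, with p-values adjusted over the 25 lists. Of the 15 lists past the test with the preset correlation, 0 passed with an estimated correlation. The latter test draws its degrees of freedom from the few arrays, not from the genes. In the inhibitory (-0.026), cytotoxic (-0.017), cytokine receptor (-0.028) and trafficking (-0.004) lists the estimate lay below the preset 0.01. The inhibitory adjusted p still went from 4.7e-04 to 0.134. In the other lists of the 15 the estimate was higher. These losses alone therefore do not show that correlation between genes made the calls. Counts of members past the test are given over all genes and adjusted over the list alone. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.

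The design, the lists, the genes to name and most alternatives were fixed before the data were examined. Named were Eomes, then genes fixed whatever their result, among them Tbx21, Ifng, Il17a, Il2rb, Klrb1c, Cd27, Cd44 and Ccr6. Next came the 12 largest rises and 12 largest falls among called genes with a plain symbol, the same direction in all 3 sorts and a measured signal on all 3 arrays of the higher group. From each list, up to 4 called members with the greatest difference followed, or the 2 with the highest signal where none was called. Some genes that this rule names are left out of the text. The lists were killer-cell receptors, cytotoxic effectors, type 1 programme, type 17 programme, naive and early T cell, activation and memory, inhibitory receptors and exhaustion, TCR signalling response, proliferation, chemokine receptors and trafficking, cytokine receptors, T cell transcription factors, γδ TCR chains, and CD3 and TCR signalling. Further lists held interferon-stimulated genes, glycolysis, cholesterol synthesis, ribosomal proteins, sorting stress genes, sex-linked transcripts, and markers of B cells, myeloid cells, erythroid cells, αβ T cells, and NK cells and ILC1. Lists share members, and Eomes is in none. Some names were not on the array, among them 18 of the 23 γδ chain names.

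The sample numbers pair the arrays. Deviations from the group mean correlated at 0.812, 0.818 and 0.808 across genes between arrays of the same sort and at -0.569 to -0.26 between arrays of different sorts, and the labels give both arrays of a number the same age and RNA input. Deviations of the 3 arrays of a group sum to 0, so the negative values follow in part from the positive ones and add little. The labels name 3 independent sorts and number the samples 1 to 3 in each group, without saying in words that a number marks a sort. That reading rests on the positive correlations and on the shared age and RNA input. The sort was therefore also used as a block. Slide 1 held Eomes-negative arrays 1 and 2 and Eomes-positive array 1, slide 2 held Eomes-positive array 2, and slide 3 held both arrays of sort 3, so slide and group were partly separable and slide was also used as a block. Slide 2 held 1 array and gave no value within it. Slide 1 held Eomes-negative array 2 without its partner of sort 2. Values within slide 1, with slide as a block or without 1 array therefore also hold differences between sorts.

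Other alternatives were normexp background correction with quantile or 75th percentile scaling, quantile normalization, median scaling, other filters on dim probes, the mean of all probes of a gene, the authors' value table, a random block for sort, trended and robust variances, a minimum of 2-fold (treat), a rank test for lists, a rotation test for lists (limma's fry, which tests a list against no change and not against other genes), and leaving out each sort and each array. A 75th percentile over probes measured on all arrays was added after seeing the data, as were raising arrays below background of a partly measured group to their lowest signal well above background, counting list members under every setting and joining the sort block with an estimated correlation. The fit was tested on simulated data of 16413 genes in 10 simulations. Without a block it recovered 11.8%, 60.6% and 86.7% of changes of 1, 2 and 4 log2 units with 0.0945% false calls. With the sort as a block it recovered 71.0%, 97.3% and 99.4% with 5.76% false calls. Camera called a shifted list in 10 of 10 simulations and an unshifted list in 0 of 10. The simulated genes varied independently of each other, so these simulations do not test the preset correlation. Estimated correlations of the real lists went up to 0.50 for proliferation, 0.71 for myeloid markers and 0.97 for ribosomal proteins.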

Results

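Transcript levels were measured in γδ T cells from the spleen of reporter mice in which green fluorescent protein (GFP) marks cells that express the T-box transcription factor Eomes. GFP-positive (Eomes-positive) and GFP-negative (Eomes-negative) γδ T cells were obtained in 3 independent sorts, which gave 3 arrays per group and 6 in all. Each array was a one-colour Agilent mouse array with 39429 probes. Between 47.7% and 56.6% of probes were well above background per array. Sorts 1 and 2 used 9 ng of RNA and had raw 75th percentiles of 1581 to 1684 intensity units, and sort 3 used 4 ng and had 534 and 549, so the mean was 3.02 times as high with the larger input. The number of arrays limits the precision of every value. Levels below are log2 signal relative to the 75th percentile of the same array, differences are Eomes-positive minus Eomes-negative, and errors of levels are SD over 3 arrays.

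The comparison asked which transcripts differ between γδ T cells sorted as positive and as negative for the Eomes reporter. Eomes transcript was well above background on all 3 Eomes-negative arrays too. Eomes itself was 27.1-fold higher in the Eomes-positive cells, at 4.91 ± 0.42 against 0.15 ± 1.12 (n = 3 each), a log2 difference of 4.76 (SE 0.59, limma adjusted p = 0.0178). Its probe lies at positions 118394425 to 118394484 of chromosome 9 in the mm9 build, and the other Eomes probe, at 118395189 to 118395248, gave 4.98. The Eomes difference was 4.59, 4.07 and 5.62 in sorts 1, 2 and 3. Within slide 1, which held 1 Eomes-positive and 2 Eomes-negative arrays, it was 4.51, and within slide 3 it was 5.62. With slide as a block the Eomes log2 difference was 4.98 (limma adjusted p = 0.0127). The difference of 4.76 had an SE of 0.33 with the sort as a block (limma adjusted p = 0.0093). Fits that left out a sort or an array used no block. Leaving out a sort or an array gave Eomes differences of 4.11 to 5.12 with limma adjusted p-values of 0.0156 to 0.251, and the call ended without sort 1 (0.251), without sort 2 (0.153), and without Eomes-negative array 1 (0.0587) or Eomes-positive array 1 (0.0887), 2 (0.0673) or 3 (0.0572).

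Among other genes fixed in advance, Tbx21, Il2rb and Klrb1c were higher in Eomes-positive cells, and the chemokine receptor gene Ccr6 was far lower. Tbx21, which encodes the T-box factor T-bet, rose by 1.12 (SE 0.19, limma adjusted p = 0.0447). Il2rb, the β chain of the IL-2 and IL-15 receptors, rose by 1.42 (SE 0.16, adjusted p = 0.014), and Klrb1c, the NK1.1 receptor gene, rose by 1.66 (SE 0.18, adjusted p = 0.0129). Ccr6 fell 86.4-fold, from 3.60 ± 0.52 to -2.83 ± 1.46, a log2 difference of -6.43 (SE 0.75, adjusted p = 0.0145). Over 23 other settings, the limma test was passed by Tbx21 in 11 (adjusted p up to 1), Il2rb in 13 (up to 0.898), Klrb1c in 15 (up to 0.366) and Ccr6 in 16 (up to 0.22). These settings include the minimum of 2-fold, which tests against 2-fold and not against no change. All 4 passed with the sort as a block. Their limma adjusted p-values were then 0.0228 for Tbx21, 0.0119 for Il2rb, 0.0133 for Klrb1c and 0.0111 for Ccr6. The omissions that follow were fitted without a block. Without 1 of the sorts, the highest limma adjusted p was 0.457 for Tbx21 and 0.234 for Il2rb. Each of these 4 calls was lost without any 1 of the sorts, with 2 arrays left per group, while the log2 differences were 0.927 to 1.13 times those above for Tbx21, 0.961 to 1.08 times for Il2rb, 0.902 to 1.06 times for Klrb1c and 0.898 to 1.09 times for Ccr6. The Tbx21 call was also lost without any 1 of the arrays, that of Il2rb without any but Eomes-positive array 2, that of Klrb1c without any but Eomes-negative array 2 or Eomes-positive array 3, and that of Ccr6 without any but Eomes-positive array 1 or 2, with log2 differences of 0.879 to 1.13 times those above over these 4 genes. Ifng, the interferon-γ gene, differed by 0.70 (SE 0.19), which did not pass the test without the sort as a block (adjusted p = 0.185) and did with it (0.0393). Cd27 differed by 0.12 (SE 0.24, adjusted p = 0.972) and Cd44 by -0.42 (SE 0.39, adjusted p = 0.868). Il17a was not well above background on any of the 6 arrays and was not tested.

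**Figure D1:**
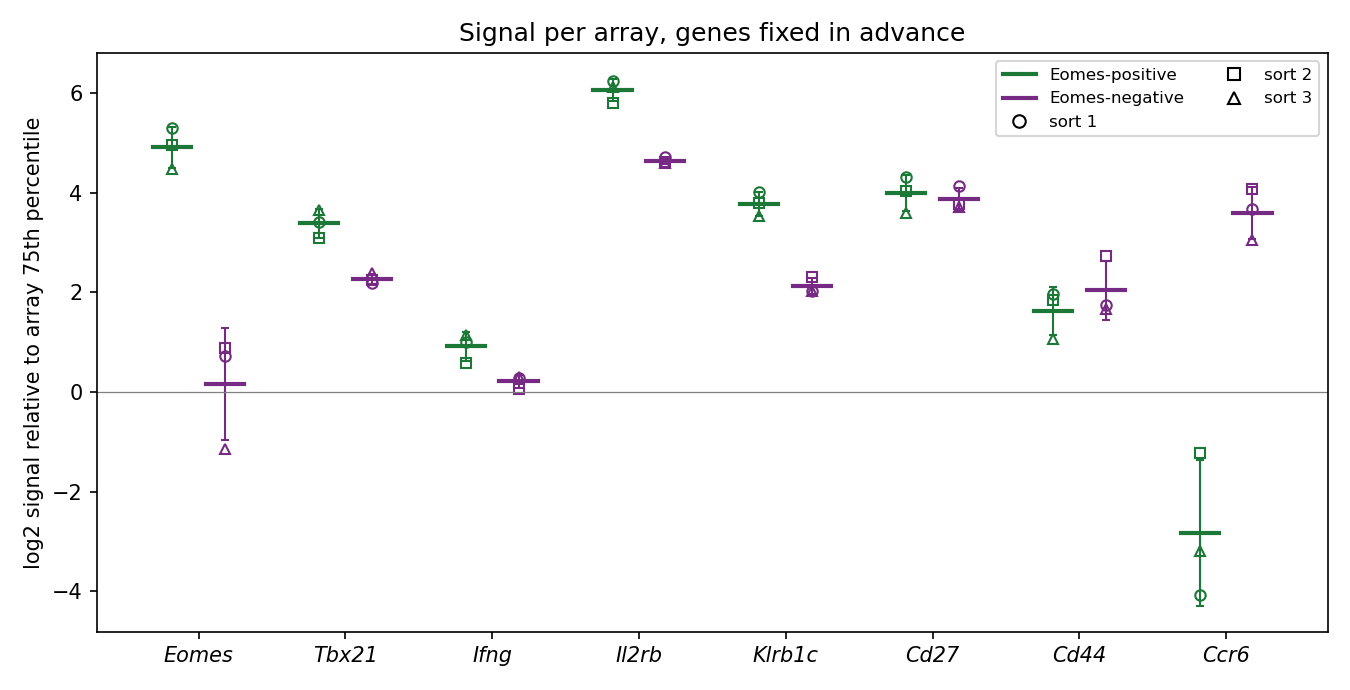
Log2 signal relative to the array 75th percentile for 8 genes fixed in advance and tested, with 1 point per array (shape gives the sort) and bars for the mean and SD of 3 arrays. Eomes-positive arrays average 4.91 for Eomes against 0.15, and -2.83 for Ccr6 against 3.60.

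Of 16413 genes tested, 197 were higher and 257 were lower in Eomes-positive cells (limma adjusted p under 0.05), each in the same direction in all 3 sorts. Of these, 179 higher and 247 lower genes differed by over 2-fold, and 2009 genes had an unadjusted p under 0.05. With the sort as a block, 600 were higher and 710 lower, among them 197 and 254 of the genes called without it. With slide as a block, 173 were higher and 255 lower. Without sort 3, the pair with less RNA, 41 were higher and 28 lower. Without sort 1 or without sort 2, limma called 0 genes, with 1354 and 1267 genes at an unadjusted p under 0.05. The median log2 difference over all genes was -0.0126.

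Among the called genes with plain symbols, the 12 largest rises included genes of secreted, membrane and enzyme proteins, and 5 of the 12 largest falls, Il23r, Il1r1, Il17re, Ccr10 and Ccr6, were in cytokine or chemokine receptor genes. Smoc2, a secreted matrix protein, was at least 50.4-fold higher (limma adjusted p = 0.00129). For such bounds, the p-value is that of the fitted difference, which includes signal below background. The Smoc2 bound is a log2 difference of 5.66, and over other settings the difference went down to 3.45. The TGF-β binding protein gene Ltbp1 was at least 31.0-fold higher, the Fc receptor-like gene Fcrl6 at least 22.1-fold, the ephrin gene Efna5 at least 18.02-fold, Gpr12 at least 17.9-fold and Wnt9a at least 12.2-fold. Over other settings their log2 differences went below these bounds, to 2.77, 2.50, 2.06, 2.13 and 1.86 in the same order. Gja5, a connexin, was well above background on 1 Eomes-negative array, and the carboxylesterase genes Ces2b and Ces2c on 2 each. With the Eomes-negative arrays raised to their lowest signal well above background, these 3 rose by 6.20, 5.99 and 5.63. Of the 12 rises, 3 were measured on all 6 arrays, Eomes, the kinase gene Mapk12 (25.1-fold, SE 0.24) and the granzyme gene Gzmm (25.1-fold, SE 0.30).

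Kcnk1, a potassium channel, was at least 103-fold lower in Eomes-positive cells (limma adjusted p = 0.0019). The interleukin receptor genes Il1r1 and Il23r were at least 60.0-fold and 58.6-fold lower, Lingo4 at least 48.6-fold, Mal at least 46.7-fold and Abi3bp at least 37.6-fold. Over other settings the log2 differences of Kcnk1 and these genes were as small as -4.3, -3.79, -3.81, -3.33, -3.37 and -3.06, short of their bounds. Itgae, an integrin chain that binds epithelial cadherin, fell, as did the kinase gene Blk, the chemokine receptor gene Ccr10, Il17re and Cpe, each well above background on 1 Eomes-positive array. With the Eomes-positive arrays raised to their lowest signal well above background, their log2 differences were -6.71, -6.78, -6.73, -6.33 and -6.07. Of the 12 falls, 1, Ccr6, was measured on all 6 arrays, and the place of the others among the 12 rests in part on signal below background.

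**Figure D2:**
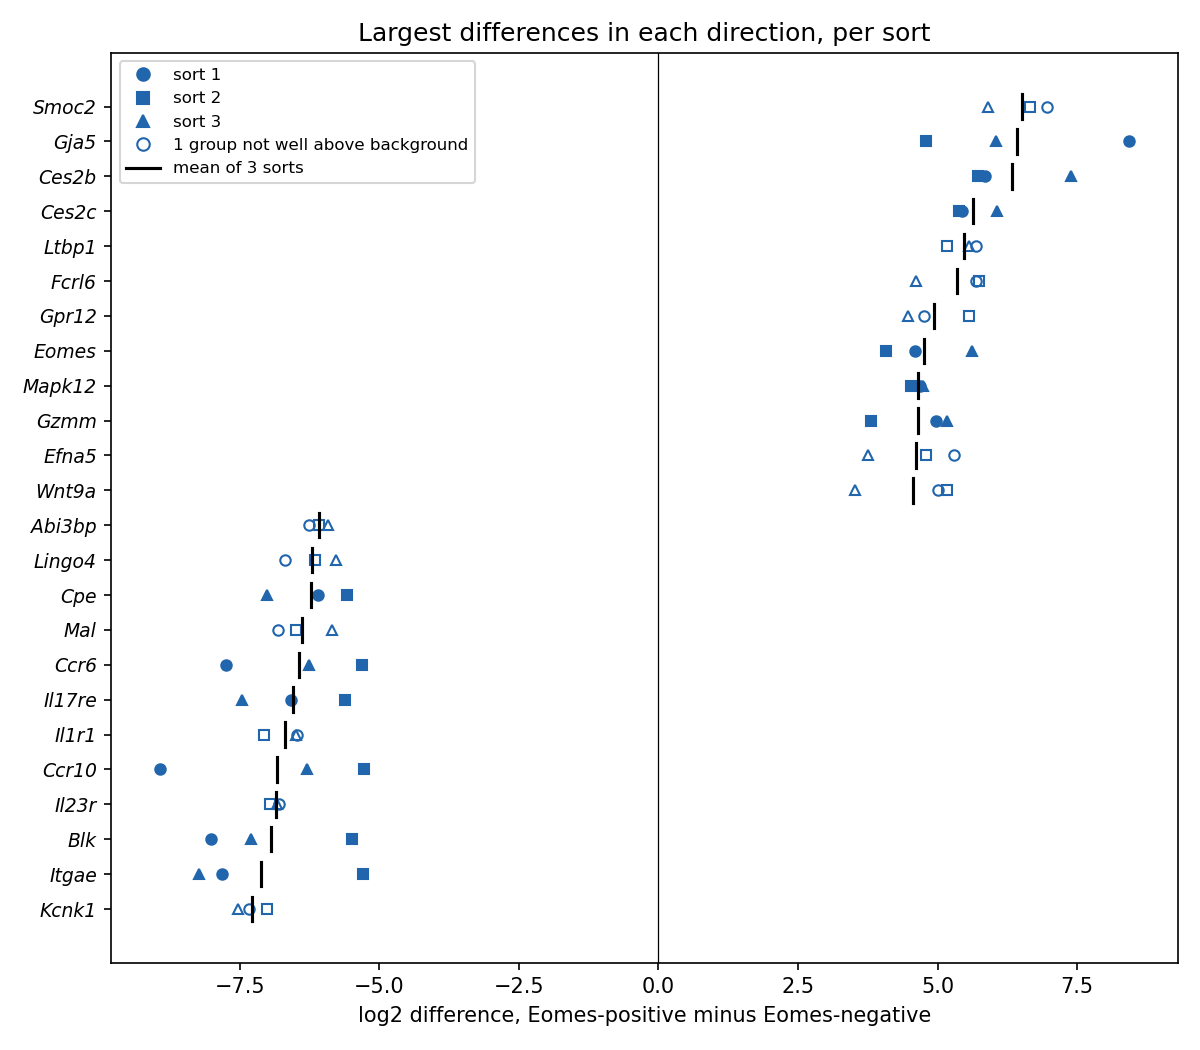
Log2 difference between the Eomes-positive and Eomes-negative array of each sort for the 12 largest rises and falls, with a bar at the mean of 3 sorts and open symbols where 1 group was not well above background. Every point lies on the side of its mean, because the choice of these genes required the same direction in all 3 sorts. The mean is -6.43 for Ccr6 and 4.76 for Eomes, both measured on all 6 arrays. Differences with open symbols rest on signal below background in 1 group.

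Genes of the type 17 programme, fixed in advance as a list of cytokine, receptor and regulator genes of cells that make IL-17, were lower in Eomes-positive cells. Of 40 tested, 21 fell and 0 rose, with a median log2 difference of -3.17, or -2.78 with genes below background at their bound, and 33 fell and 1 rose adjusted over the list alone. Besides Kcnk1, Blk, Il23r and Il1r1, the members that fell included the transcription factor genes Zbtb16 (-3.83), Maf (-2.93) and Rora (-2.23). With the sort as a block 30 fell and 1 rose. Without sort 1 or without sort 2 limma called 0 members, as for all genes, without sort 3 it called 6, and without Eomes-negative array 2 or 3 it called 13 each. The type 17 list was lower than other genes (camera adjusted p = 1.6e-32), and that call was lost with an estimated correlation (adjusted p = 0.0762). The list median was -3.64 within slide 1, -3.11 within slide 3 and -3.50 with slide as a block. Markers of αβ T cells, which the sort gate excluded by TCRβ and by CD4 and CD8β depletion, were also lower, with a median of -0.41 over 12 genes, and 1 of them, Cd8b1, fell (-2.86, SE 0.36, limma adjusted p = 0.0194). Of those 12, 0 rose, 1 fell adjusted over the list alone, and 2 fell with the sort as a block. The αβ list was lower than other genes (camera adjusted p = 0.040), a call lost with an estimated correlation (adjusted p = 0.222), with the sort as a block (0.0505) or as a random block (0.0893), by a rank test (0.0517), with genes measured on all 6 arrays (0.0673), without sort 1 (0.103), and without Eomes-negative array 1 (0.0537) or Eomes-positive array 1 (0.0854) or 3 (0.0525). Its median was -0.37 within slide 1 and -0.64 within slide 3.

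Killer-cell receptor genes were higher in Eomes-positive cells. Of 35 tested, 10 rose and 0 fell, with a median difference of 0.98, and 19 rose adjusted over the list alone. The C-type lectin receptor genes Klre1 (4.33, SE 0.34), Klri1 (3.39, SE 0.36), Klri2 (2.88, SE 0.48) and Klrc1 (2.78, SE 0.19) had the greatest rises. Limma called 0 members without any 1 of the sorts and 3 to 5 without any 1 of the arrays. The killer-receptor list was higher than other genes (camera adjusted p = 3.1e-15), and the call was lost with an estimated correlation (adjusted p = 0.134). The median was 0.86 within slide 1, 1.31 within slide 3 and 0.91 with slide as a block. Markers of NK cells and ILC1, which lack the CD3 and TCRγδ that the gate required, were higher too, with a median of 0.97 over 19 genes, of which 9 were also killer receptors. Of these 19, 3 rose (Klre1, Klri2 and Styk1, the last well above background on 2 Eomes-negative arrays) and 0 fell, with 6 that rose adjusted over the list alone and 6 with the sort as a block. The NK list was higher than other genes (camera adjusted p = 1.4e-06, or adjusted p = 0.269 with an estimated correlation), and a rotation test against no change gave an adjusted p of 0.0607. The NK median was 0.63 without Eomes-positive array 2, 0.60 without Eomes-negative array 3, 0.65 within slide 1 and 1.18 within slide 3.

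Several genes of the type 1 programme and 3 of the cytotoxic effectors were higher in Eomes-positive cells. Of 27 type 1 genes tested, 7 rose and 1 fell, with a median of 0.36, and 12 rose and 3 fell adjusted over the list alone, while 8 rose and 3 fell with the sort as a block. Slamf7 rose by 2.38 (SE 0.30) and the chemokine gene Xcl1 by 1.69 (SE 0.21). The IL-18 receptor gene Il18r1, also in the type 17 list, fell (-1.75, SE 0.28). Limma called 0 members of the type 1 list without any 1 of the sorts, and 1 to 3 higher without any 1 of the arrays. The type 1 list was higher than other genes (camera adjusted p = 1.1e-05), a call lost with an estimated correlation (adjusted p = 0.173). Its median was 0.48 within slide 1, 0.36 within slide 3, 0.53 with slide as a block, 0.65 with the mean of all probes and 0.57 without Eomes-negative array 3. Of 20 cytotoxic effector genes, 3 rose and 0 fell, with a median of 0.18, namely Gzmm (4.65), the death ligand gene Tnfsf10 (1.77, SE 0.18) and Stx11 (1.36, SE 0.22). Adjusted over the list alone, 7 rose and 2 fell, and with the sort as a block 7 rose and 3 fell. Without any 1 of the sorts 0 rose, and 1 rose without Eomes-positive array 1 or Eomes-negative array 2. The cytotoxic list was higher than other genes (camera adjusted p = 0.0116), and the call was lost with an estimated correlation (adjusted p = 0.173), with the sort as a block (adjusted p = 0.159), by a rank test (adjusted p = 0.184) and without sort 3 (median 0.12, adjusted p = 0.0762). Its median was 0.11 within slide 1, 0.39 within slide 3, 0.20 with slide as a block and 0.28 with median scaling, and it was 0.28, 0.29 and 0.35 without Eomes-positive array 1, Eomes-positive array 2 and Eomes-negative array 2.

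Receptors that guide cell migration changed in both directions. Of 33 chemokine receptor and trafficking genes, 4 rose and 7 fell, with a median of -0.65, 8 rose and 14 fell adjusted over the list alone, and 7 rose and 12 fell with the sort as a block. Of the 33, 4 were also members of the type 17 list. Itgae, Ccr10 and Ccr6 fell as given above, and Ccr4 was at least 23.6-fold lower. Of the 4 that rose, 3 were named after their values were seen, S1pr5 (4.18, SE 0.69), the follicle-homing receptor gene Cxcr5 (4.18, SE 0.28) and the integrin gene Itgax (3.65, SE 0.61). The trafficking list was lower than other genes (camera adjusted p = 0.040), a call lost with the sort as a block (adjusted p = 0.063), with an estimated correlation (adjusted p = 0.173), with genes measured on all 6 arrays (0.827), by a rank test (0.153), without sort 2 (0.0522) and without Eomes-negative array 2 (0.17) or 3 (0.0794). The trafficking median was -0.40 with genes measured on all 6 arrays, -0.42 with no filter or without Eomes-positive array 2, -0.46 within slide 1 and -0.48 within slide 3. Of 29 cytokine receptor genes, 2 rose and 8 fell, with a median of -0.13, and 6 rose and 10 fell adjusted over the list alone, while 4 rose and 10 fell with the sort as a block. Of the 29, 5 were also members of the type 17 list. Besides Il23r, Il1r1 and Il17re, Il17rb was at least 12.5-fold lower, and the 2 that rose, named after their values were seen, were Il10ra (1.82, SE 0.21) and Il2rb. The cytokine receptor list was lower than other genes (camera adjusted p = 0.036), a call lost with the sort as a block (adjusted p = 0.125), with an estimated correlation (adjusted p = 0.173), with genes measured on all 6 arrays (median -0.0052, adjusted p = 0.827), by a rank test (0.287) and without sort 3 (median -0.06, adjusted p = 0.0549). The cytokine receptor median lay at -0.27 to -0.02 without 1 sort or array, at -0.03 with median scaling and at -0.06 with no filter on dim probes, and it was -0.11 within slide 1 and -0.33 within slide 3.

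Of the TCR γ chain variable genes, 2 were lower in Eomes-positive cells, as were 4 transcription factor genes. A total of 5 of 23 γδ TCR chain names were on the array, and of these 2 fell and 0 rose, also adjusted over the list alone: Tcrg-V6 (-4.02, SE 0.43), also in the type 17 list, and Tcrg-V5 (-2.24, SE 0.22). Tcrg-V1 differed by -0.07 (SE 0.45), Tcrg-V2 by -0.34 (SE 0.24) and Tcrg-V7 by -0.29 (SE 0.25), and these 3 did not pass the test. The chain list was lower than other genes (camera adjusted p = 0.00194, or adjusted p = 0.173 with an estimated correlation). Its median of -0.34 was -0.52 without Eomes-negative array 2, -0.19 without Eomes-positive array 2 or with slide as a block, -0.10 within slide 1 and -0.37 within slide 3. Of 47 T cell transcription factor genes, 2 rose and 4 fell, while 6 rose and 6 fell adjusted over the list alone and 5 rose and 8 fell with the sort as a block. Of the 47, 9 were also members of the type 17 list. Hlf was at least 19.3-fold lower, and Zbtb16, Maf and Rora fell as given above. The 2 that rose were Tbx21 and Myb (2.03, SE 0.34), the latter named after its value was seen. The transcription factor list had a median of 0.01 and a mean of -0.27 and did not pass the test against other genes (camera adjusted p = 0.651), while a rotation test against no change gave an adjusted p of 0.0309. Its median was 0.06 within slide 1, -0.12 within slide 3 and -0.10 to 0.11 over other settings. Of 30 genes of CD3 and TCR signalling, 2 rose, Fyn (1.37, SE 0.17) and Txk (1.36, SE 0.16), and 1 fell, Sit1 (-2.19, SE 0.25), with 3 and 4 adjusted over the list alone and 3 and 5 with the sort as a block (camera adjusted p = 0.275, or 0.0498 without Eomes-negative array 2).

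**Figure D3:**
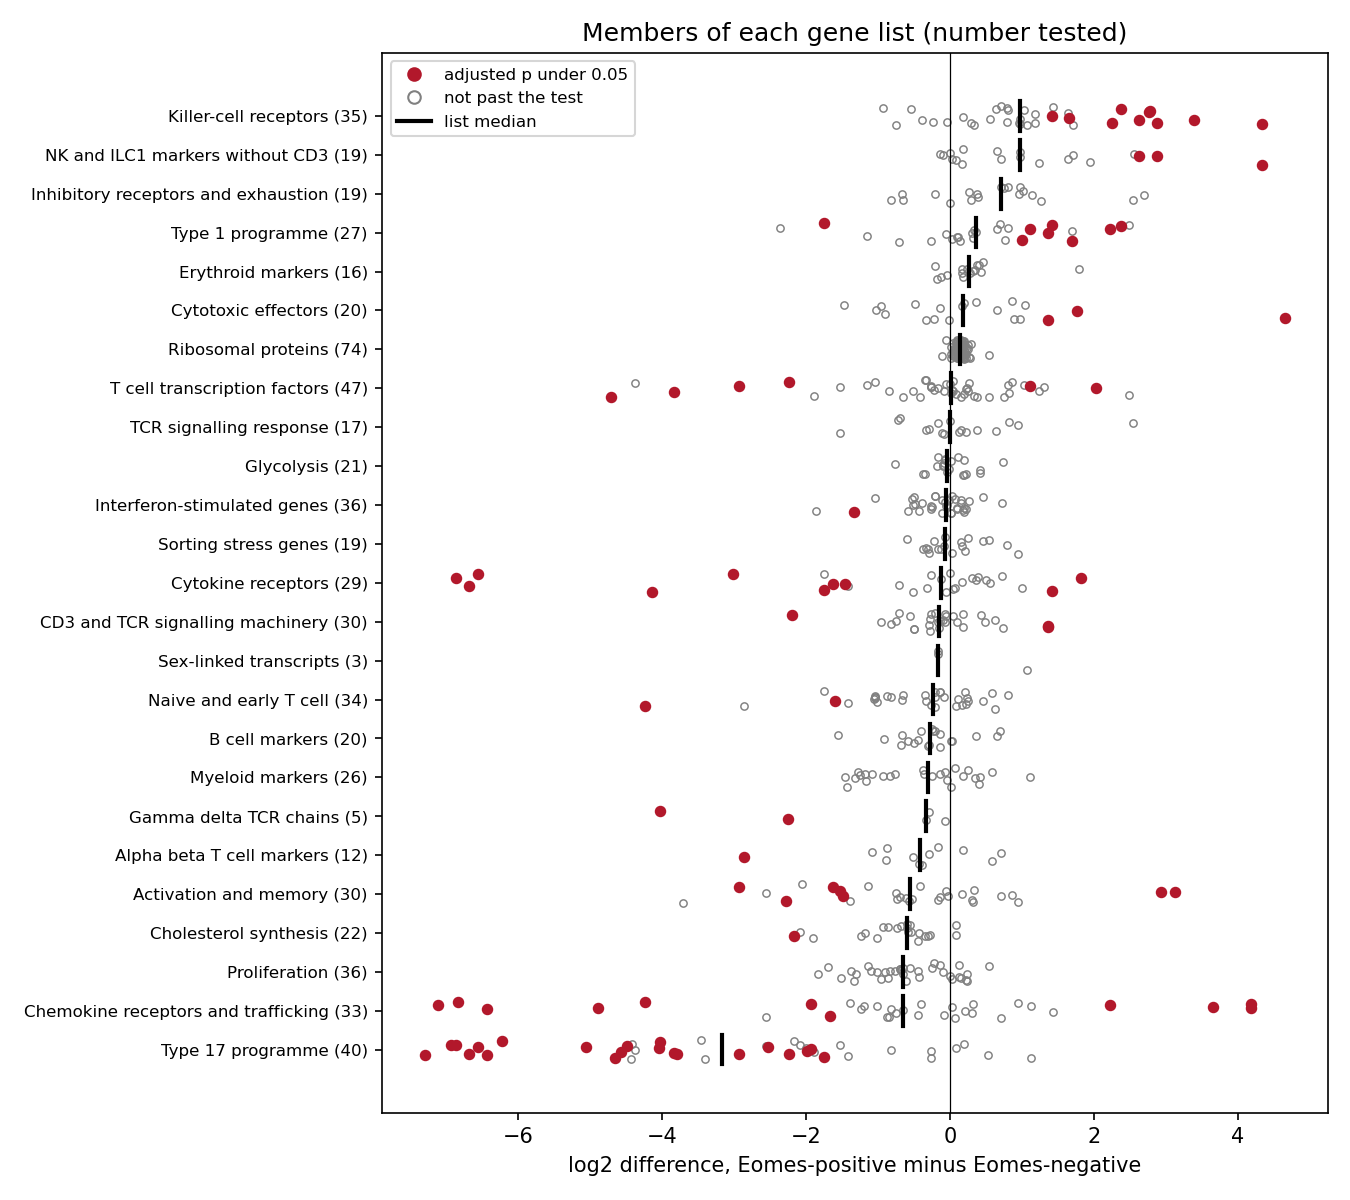
Log2 difference of each tested member of the 25 gene lists, with filled points for members past the test and a bar for the list median. The type 17 programme has the lowest median, -3.17, and the killer-cell receptors have the highest, 0.98.

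Naive, activation, inhibitory and proliferation genes were tested as further lists. Of 34 naive and early T cell genes, 2 fell and 0 rose, with a median of -0.24. They were the gut and thymus homing receptor gene Ccr9 (-4.23, SE 0.50) and Tdrp (-1.60, SE 0.22). For this list 7 fell adjusted over the list alone, and 1 rose and 11 fell with the sort as a block (camera adjusted p = 0.00226, or adjusted p = 0.481 with an estimated correlation and 0.0537 without Eomes-negative array 1), and the rotation test against no change gave 0.101. The naive median was -0.14 with median scaling, -0.36 without Eomes-negative array 2, -0.19 within slide 1 and -0.31 within slide 3. Of 30 activation and memory genes, 2 rose and 5 fell, with a median of -0.55, while 5 rose and 8 fell adjusted over the list alone and 5 rose and 13 fell with the sort as a block. Ctla2b (3.12, SE 0.18) and Ctla2a (2.93, SE 0.19) rose, and Capg (-2.93, SE 0.45) and S100a6 (-2.28, SE 0.30) fell. The activation list was lower than other genes (camera adjusted p = 0.040), a call lost with an estimated correlation (adjusted p = 0.473), by a rank test (0.0554), with the sort as a random block (0.121), with the mean of all probes (0.0657), without sort 3 (0.0579), and without Eomes-positive array 1 (0.0979) or Eomes-negative array 2 (0.14) or 3 (0.126). Its median was -0.52 within slide 1 and -0.63 within slide 3, and the rotation test against no change gave 0.622. Of 19 genes of inhibitory receptors and exhaustion, 0 passed the limma test over all genes (7 higher and 1 lower at an unadjusted p under 0.05), 7 rose and 1 fell adjusted over the list alone, and 7 rose and 1 fell with the sort as a block. Pdcd1, which encodes PD-1, differed by 0.97 (SE 0.22, limma adjusted p = 0.108, or 0.0188 with the sort as a block), and Nr4a1 by 0.38 (SE 0.20). The inhibitory list had a median of 0.72 and was higher than other genes (camera adjusted p = 4.7e-04, or adjusted p = 0.134 with an estimated correlation). That median was 0.41 with normexp background correction and 75th percentile scaling, 0.46 with normexp and quantile normalization, 0.61 within slide 1 and 0.73 within slide 3. Of 36 proliferation genes, 0 rose and 0 fell by limma, also adjusted over the list alone (1 lower at an unadjusted p under 0.05), and 8 fell with the sort as a block, with a median of -0.65 (camera adjusted p = 0.0208). This call was lost with an estimated correlation (adjusted p = 0.884), without sort 3 (0.103), and without Eomes-positive array 1 (median -0.21, adjusted p = 0.471) or Eomes-negative array 2 (-0.30, 0.341) or 3 (0.0544). The proliferation median was -1.01 without Eomes-negative array 1, -0.41 with normexp and quantile normalization, -1.45 within slide 1, -0.38 within slide 3 and -1.02 with slide as a block, and the rotation test against no change gave 0.622. The replication genes Mcm6 and Pcna differed by 0.24 (SE 0.26) and -0.10 (SE 0.14).

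B cell, myeloid and erythroid markers gave 0 calls over all genes. H2-Ab1 was at 5.70 and 5.44 on Eomes-negative and Eomes-positive array 2, against 2.39 and 1.60 on array 1. Hba-a2 was at 7.67 and 7.50, against 4.67 and 4.66. Values within slide 1, with slide as a block or without 1 array thus mix in differences between sorts. Between the 2 arrays of sorts 1 to 3, medians were -0.88, -0.22 and 0.29 for B cell and 0.07, -0.11 and 0.80 for erythroid markers. Of 20 B cell markers, 0 rose and 0 fell by limma (1 in each direction at an unadjusted p under 0.05), with 1 that fell adjusted over the list alone and 1 in each direction with the sort as a block, and a median of -0.27 (camera adjusted p = 0.741). The median of the B cell markers was -2.13 within slide 1, 0.29 within slide 3 and -1.03 with slide as a block. It was 0.05 and -0.63 without sort 1 and sort 3, 0.48, -0.88 and -0.46 without Eomes-positive arrays 1, 2 and 3, and -0.94, 0.40 and -0.43 without Eomes-negative arrays 1, 2 and 3. H2-Ab1 differed by -0.21 (SE 1.24, or 0.26 with the sort as a block) and Cd79b, a B cell receptor component, by -0.92 (SE 0.17, limma adjusted p = 0.0598, or 0.0217 with the sort as a block). Of 26 myeloid markers, 0 rose and 0 fell by limma, also adjusted over the list alone and at an unadjusted p under 0.05, and 1 rose with the sort as a block. Their median was -0.31 (camera adjusted p = 0.595), with -0.49, -0.62 and 0.89 in sorts 1 to 3, -2.67 within slide 1 and 0.89 within slide 3, and with slide as a block it was -1.47 and passed the test (adjusted p = 0.0276), as it did without Eomes-positive array 2 (-1.64) or Eomes-negative array 3 (-1.08). The myeloid median was -0.08, -0.18 and -0.59 without sorts 1, 2 and 3, -0.02 and -0.20 without Eomes-positive arrays 1 and 3, and -0.82 and 0.35 without Eomes-negative arrays 1 and 2. Siglech differed by 0.01 (SE 0.31) and Csf3r by -0.14 (SE 0.31). Signal of both was high in both groups. Siglech was at 5.81 in Eomes-positive and 5.79 in Eomes-negative cells, and Csf3r at 5.37 and 5.51. Of 3 Siglech probes, only 1 was well above background on all 3 arrays of a group. Of 16 erythroid markers, 0 rose and 0 fell by limma, also adjusted over the list alone (1 higher at an unadjusted p under 0.05), with a median of 0.26 (camera adjusted p = 0.595), which passed without Eomes-positive array 1 (1.46) or Eomes-negative array 2 (1.14). That median was 0.45 and -0.03 without sorts 2 and 3, -0.39 and -0.23 without Eomes-positive arrays 2 and 3, and -0.77 and 0.45 without Eomes-negative arrays 1 and 3. The median of the erythroid markers was -1.68 within slide 1, 0.80 within slide 3 and -0.64 with slide as a block, and the haemoglobin genes Hba-a2 and Hba-a1 differed by 0.16 (SE 1.16) and 0.24 (SE 1.25). Their SEs were 0.20 and 0.19 with the sort as a block.

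Ribosomal, stress and sex-linked genes gave 0 calls over all genes without a block. Of 74 ribosomal protein genes, 0 rose and 0 fell by limma, also adjusted over the list alone and at an unadjusted p under 0.05, and their median of 0.14 passed the set test (camera adjusted p = 0.040). The call was lost with an estimated correlation (adjusted p = 0.884), with the sort as a random block (0.0893), with genes measured on all 6 arrays (0.0673), with the mean of all probes (0.0608), without sort 1 (0.125) and without Eomes-negative array 2 (0.259). That median was 0.0046 with normexp background correction and quantile normalization and 0.0097 with quantile normalization, 0.24 with median scaling, and -0.12 to 0.38 without 1 of the arrays, below 0 without Eomes-negative array 1 (-0.05) and without Eomes-positive array 3 (-0.12). A rotation test of these genes against no change gave an adjusted p of 0.919. Rplp2 and Rps16 each differed by 0.15. Of 19 stress genes of cell sorting, 0 rose and 0 fell by limma, also adjusted over the list alone (1 higher at an unadjusted p under 0.05), and 1 rose with the sort as a block, with a median of -0.07, which other scalings moved as far as 0.03, and a mean of 0.05 (camera adjusted p = 0.768), and the chaperone genes Hspa8 and Hspe1 differed by 0.17 (SE 0.25) and 0.21 (SE 0.17). Of 3 sex-linked transcripts tested, 0 rose and 0 fell by limma, also adjusted over the list alone and at an unadjusted p under 0.05 (median -0.17, mean 0.24, camera adjusted p = 0.818), with Eif2s3y at -0.17 (SE 0.35) and Ddx3y at -0.17 (SE 0.20).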

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

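The settings were planned, except for a 75th percentile over probes measured on all arrays, the counts of list members, the raising of dim arrays to background and the block joined with an estimated correlation, chosen after seeing the data. No called gene was called in the other direction in any setting, and scalings moved the median of all genes by less than 0.1. Counts of 197 higher and 257 lower genes became 92 and 154 with no filter on dim probes, where 30342 genes were tested, 166 lower with a signal on all 6 arrays, where 13783 were tested, and 45 and 76 with a minimum of 2-fold. With the sort as a replicate block they were 600 and 710, and with a random replicate block 1063 and 1131. The blocks took up the shared deviation of the 2 arrays of a sort (within-pair correlation 0.742). The fixed block ended the calls of the cytotoxic list (0.18), the trafficking, cytokine receptor and αβ T cell lists, made calls of Ifng, Pdcd1, Dusp2 and Cd79b, and changed no other call of a named gene or list. Leaving out a sort or an array, fitted without a block, gave 0 to 101 higher and 0 to 180 lower genes, with 0 and 0 called by limma without sort 1 or 2 (1354 and 1267 genes at an unadjusted p under 0.05). The cause was not tested.

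Eomes stayed at 4.11 to 5.12 over these omissions and at 4.76 with the 2-fold minimum (adjusted p = 0.0558), with limma adjusted p-values of 0.000589 to 0.251 over all settings. Of 15 lists past the test, 0 passed with an estimated correlation, alone or with the sort as a replicate block, which gave the type 17 (-3.17), killer-receptor (0.98), type 1 (0.36) and cytotoxic (0.18) medians adjusted p-values of 0.0762 to 0.64. That test is limited by the few arrays, so these losses alone do not show that correlation between genes made the calls. The list calls rest on the preset correlation. The other settings gave 10 to 16 lists. The cytotoxic list (0.18) missed the rank test (adjusted p = 0.184) and ranged from 0.12 to 0.35 over the omissions. The ribosomal median of 0.14 was 0.0046 with normexp and quantile normalization and -0.12 to 0.38 over the omissions, with the set test pointing down in the former, without Eomes-negative array 1 (-0.05) and without Eomes-positive array 3 (-0.12). The cause was not tested. For other named genes and lists, 1525 of 1861 gene values and 467 of 546 list values stayed on their side of the test, of which 35 and 22, past it in neither fit, changed sign. A further 322 and 63 passed the test no more, and 14 and 13 newly passed it, with lists counted also under a rotation test, which tests against no change and not against other genes. The 4 ng arrays had the lowest share of probes well above background, 47.7%, which limits dim genes.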

Other observations

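Of 22 genes of cholesterol synthesis tested, 1 fell over all genes by limma and 0 rose, while 12 fell adjusted over the list alone and 7 with the sort as a block. The list median was -0.59 (camera adjusted p = 5.1e-11, or adjusted p = 0.173 with an estimated correlation), with -0.60 within slide 1 and -0.59 within slide 3. Of 36 interferon-stimulated genes, 1 fell, Isg20 (-1.33, SE 0.22), and 0 rose, also adjusted over the list alone, with 1 higher and 2 lower with the sort as a block. Their median was -0.06, or as far as 0.04 under other scalings (camera adjusted p = 0.0839), and the list passed the test as lower with normexp and 75th percentile scaling (0.0494), with no filter on dim probes (0.019), without sort 3 (0.0267), and without Eomes-positive array 1 (0.043) or 3 (0.0351) or Eomes-negative array 2 (0.0076). Of 21 glycolysis genes, limma called 0 (2 higher at an unadjusted p under 0.05), also adjusted over the list alone, and 1 higher with the sort as a block. Their median was -0.03, which changed sign under 2 scalings (to 0.06 at most), their mean was 0.01 (camera adjusted p = 0.640), and Ldha differed by -0.17 (SE 0.12). Of 17 genes of the response to TCR signalling, limma called 0 (2 higher and 2 lower at an unadjusted p under 0.05), 1 rose adjusted over the list alone, and 1 rose and 3 fell with the sort as a block. Their median was 2.83e-04 (camera adjusted p = 0.768), with -0.22, 0.25 and 0.01 in sorts 1 to 3 and up to 0.10 under other scalings. Nfkbia differed by -0.17 (SE 0.24) and Dusp2 by -0.72 (SE 0.23, limma adjusted p = 0.249, or 0.0353 with the sort as a block).

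Other genes stood out after their values were seen. Dntt, which encodes the terminal transferase that adds bases to rearranging receptor genes, fell 36.5-fold (-5.19, SE 0.17, limma adjusted p = 0.0011). Tmevpg1, a long noncoding RNA gene beside Ifng, rose by 4.32 (SE 0.28, limma adjusted p = 0.00268) and was well above background on 2 Eomes-negative arrays (4.32 also with all raised to their lowest signal well above background), while Ifng differed by 0.70. Crtam, an adhesion receptor of cytotoxic cells, rose by 3.01 (SE 0.34, limma adjusted p = 0.0134).

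The tests of slide, of αβ T cells and of NK cells were chosen after the results were seen. The splits were set before, and the thymocyte genes were listed before their values were seen but after Dntt and Ccr9 had been noticed. Dividing the 6 arrays into 3 and 3 allows 10 splits, too few for a share under 0.05. In 1 of the 10, the real one, limma called as many genes, 197 higher and 257 lower, against 0 in the highest other split, and 1 split, the real one, moved as many lists past the test, 15 against 14 in the highest other. Among the 4 splits that part all 3 pairs the highest other had 0 genes and 9 lists, and the others parted 1 pair. The split of slide 1 from the rest called 0 genes and had 2118 genes at an unadjusted p under 0.05, against 2009 for the real split, and with slide as a block 173 genes were higher and 255 lower.

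The type 17 list was lower in Eomes-positive cells (camera adjusted p = 1.6e-32, or adjusted p = 0.0762 with an estimated correlation). Both arrays of each sort had the same RNA input, so by design input did not differ between the groups. Slide as the whole cause is argued against by sorts 1 and 3, whose 2 arrays shared a slide. There the less shifted median was -3.09, with an SD of 0.229 between sorts. αβ T cells among the Eomes-negative cells stay open, although the gate required TCRγδ and excluded TCRβ: their 12 markers had a median of -0.412 (bootstrap SD 0.213) and Cd8b1 fell (-2.86), and Cd4 and Tcrb-J were measured in both populations (0.88 and 1.81 in Eomes-negative cells), so that a small share would be hidden. A first criterion, that the markers lie above the type 17 median by a set margin, would have excluded αβ T cells, and it was replaced after its result was seen because it ignored this baseline. A higher share of type 17 cells in the Eomes-negative population and a higher level per cell are biological explanations that the arrays cannot separate and that were not tested.

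Of 35 killer-cell receptor genes, 10 rose and 0 fell in Eomes-positive cells. The list was higher than other genes (camera adjusted p = 3.1e-15, or adjusted p = 0.134 with an estimated correlation). Slide as the whole cause is argued against by the same 2 sorts, where the smaller list median was 0.831, with an SD of 0.272 between sorts. NK cells among the Eomes-positive cells stay open, although the gate required CD3 and TCRγδ: their 10 markers outside the receptor list had a median of 0.126 (bootstrap SD 0.388), limma called 0 of them, and the CD3 genes had a median of -0.0677. The most abundant of these markers, Nkg7 and Gzma, were at 6.61 and 5.48 in Eomes-positive and 6.45 and 5.62 in Eomes-negative cells, so that a small share would be hidden. A difference in the γδ T cells themselves stays open as well and was not tested apart from these.

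Dntt and Ccr9, both expressed in the thymus, were lower in Eomes-positive cells. A candidate explanation is a larger share of recent thymic emigrants among Eomes-negative cells, which would lower other thymocyte genes too. The 17 thymocyte genes tested had a median of 0.151 (bootstrap SD 0.289), 8 of them below 0, and the set lay higher, not lower, than other genes (camera p = 0.0477, or p = 0.10 with an estimated correlation). Limma called 3 of them, Endou (3.18), Hes1 (2.93) and Hhex (2.22), all higher in Eomes-positive cells, with Hes1 well above background on 1 Eomes-negative array. Arpp21, below background in Eomes-positive cells, was at least 4.00-fold lower without passing the test (limma adjusted p = 0.0763), which goes with the explanation. The prediction was not met, and the explanation stays open because the median was within its spread of 0 and Rag1, Rag2, Ptcra, Erg and Notch3 were too dim to be tested.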
